A study of Mus musculus with 3 samples.

How the data were processed

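ATAC-seq libraries from NeuN-sorted nuclei of the mouse dentate gyrus were analysed for 3 replicates of a single group, the KS1 model. Per the labels' protocols, nuclei came through an iodixanol gradient, were stained for NeuN and sorted, typically 5000 per sample, and were tagmented for 30 minutes. The deposited table holds raw counts per peak on mm10, per the file header, not divided by depth or width. The submitters' processing notes name MACS2, featureCounts, Picard and SAMtools, with no version or role. The aligner, the handling of duplicates, any shift of reads for the transposase, the libraries on which peaks were called and whether reads or fragments were counted are not given in the sources used here. A single peak set serves all columns, so a peak absent from it has no count in any library. Reads outside peaks are not part of the table, so CPM here is relative to counts in peaks. All 3 columns were matched to a sample by name. Coordinates are printed as deposited, and whether starts count from 0 or 1 is not stated, which leaves them uncertain by 1 bp.

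Depth was 10857419, 6858215 and 8357165 counts, with a median count per peak of 31, 23 and 24. Replicate 2 is the shallowest, and a peak at the median rests on 23 to 31 counts per library, so values of single weak peaks carry a large counting error. Binomial intervals (95%, Wilson) and chi-square tests of counts treat counts as independent, which PCR copies are not.

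Gene positions came from a RefSeq gene table of the mouse assembly behind mm10, with 21900 protein-coding genes with positions, 21887 of them on chromosomes with peaks. The table gives spans without strand, and a genome sequence was not used here. The promoter window planned before the data were examined therefore became a window of 1000 bp on either side of both ends of each protein-coding gene. Gene spans include predicted transcripts, so a promoter inside the span can lie outside this window. At Kmt2d and Rbfox3 the strongest peak lay inside the span and outside the window, and whether it is a promoter was not tested. As a check of the coordinates, 10.1% of peaks overlapped such a window, against 4.40% and 4.37% when genes were moved by 1 Mb up or down. The planned comparisons of CpG island peaks, the variation per island class, random lists matched on islands and the correction for GC content need sequence and were not run.

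The gene's boundary peak was the overlapping peak with the highest mean CPM. Density is CPM per kb of peak width. For 15 gene lists fixed before the data were examined, the share of members with a boundary peak and the median log2 CPM of those peaks were placed among 10000 random lists of the same size, unmatched because islands were not used. The summed CPM of other peaks in the gene and 10000 bp on both sides, per kb, was placed among lists matched on gene length decile. Two-sided p-values from these lists describe these libraries and were adjusted by Benjamini-Hochberg over the 15 lists, for each measure separately. The smallest unadjusted p they can give is 0.0002. No gene is in more than 1 list. Pairs of lists were compared by the difference of mean log2 values, with pseudocounts of 1 CPM and 0.1 CPM per kb, by exact permutation where a list had fewer than 10 values and otherwise with 100000 permutations.

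Named genes were set by a rule written before the data were examined. They are Kmt2d, Kdm6a and Rbfox3, the 2 members of each list with the highest boundary-peak density and up to 2 members without such a peak, the 10 genes of highest boundary-peak density, the 10 most uneven boundary peaks, and the 5 strongest other peaks. Other members, such as Prox1, Calb1, Bdnf and Celf4, were named after their values were seen. Some genes that the rule names are not reported here. Peaks shared by neighbouring genes are named as shared, since the counts belong to the peak.

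Variation between libraries was estimated with edgeR 4.0.16 in R 4.3.3 as the square root of the common dispersion with an intercept only, without a trend, on peaks above 0.5 CPM in 2 libraries, with TMM factors of 0.980, 1.05 and 0.971. Peaks that varied were found by a Poisson chi-square test against the TMM-scaled library sizes at an adjusted p of 0.05. Alternatives used DESeq2 1.42.0 size factors, total counts, other filters, other windows and each replicate left out in turn. Counts were simulated for the same 171764 peaks, with changed peaks drawn only from those with total counts at or above the median. Each change was an increase in replicate 1 alone, the deepest library. Peaks changed 2-fold were called in 76% of cases with no added variation and in 81% with a coefficient of 15%. Peaks changed 4-fold were called in 100% of both. These rates do not cover the weaker peaks, decreases, or changes in replicates 2 and 3. With no added variation the coefficient was estimated as 0.046 and 11 unchanged peaks were called. With 0.15 it was estimated as 0.154, and 7.26% of the peaks not changed were called, so a count of variable peaks of this size also arises where all peaks vary alike. The list test was checked on 2000 simulated lists of 14 genes, of which 3.45% fell under 0.05 with no shift and 87.6% with a shift of 1 SD. A first run on 200 lists gave 1% with no shift and was enlarged for that reason. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.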

Results

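Accessible chromatin was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in neuronal nuclei of the mouse dentate gyrus. The nuclei had been sorted for NeuN, the neuronal nuclear protein encoded by Rbfox3. The 3 libraries analysed here belong to a single group, C57BL/6J mice modelling Kabuki syndrome type 1 (KS1), from the study's replication cohort. KS1 in people is caused by variants of KMT2D, which encodes a histone lysine methyltransferase. The series also concerns wild-type mice and a model of Kabuki syndrome type 2, which are not analysed here, so no value below compares genotypes. The table held counts at 172558 peaks on the mm10 assembly, with 10857419 counts in replicate 1, 6858215 in replicate 2 and 8357165 in replicate 3. Counts of 0 occurred at 15, 16 and 47 peaks in the same order. Values are given as mean ± SD over the 3 libraries (n = 3), in CPM, each count divided by the library total in peaks and multiplied by 1e6. The labels do not say that the replicates are separate animals, so the spread between them may be technical.

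The first question was how open the genes named by the disease model were. Kdm6a, which encodes a histone demethylase and is the gene behind the X-linked form of Kabuki syndrome, had a peak at its left annotated end of 84.4 ± 9.05 CPM (chromosome X, 18161599 to 18163853). That level lay at percentile 99.4 of all protein-coding genes with a peak at a gene end. Kmt2d had 8 peaks within 1000 bp of its annotated span (chromosome 15, 98831669 to 98874077). The strongest peak at an annotated end of Kmt2d, from 98830674 to 98831937, had 16.4 ± 2.94 CPM, at percentile 45.4, and is also at an end of Prkag1. Its level was 15.7 CPM in replicate 1, 13.9 in replicate 2 and 19.6 in replicate 3. A stronger Kmt2d peak of 21.7 ± 2.73 CPM lay inside the span, from 98871359 to 98872741. With a window of 2000 bp it was the peak used for Kmt2d. Percentile 45.4 thus ranks the shared peak alone. The stronger peak lay above the median of 18.3 CPM over all genes with a peak at a gene end. Rbfox3 held 107 peaks in its span (chromosome 11, 118489760 to 118911597), the strongest of 44.7 ± 6.05 CPM from 118792401 to 118794975, while the peak at its annotated end had 6.93 ± 0.991 CPM and is shared with Engase. With a window of 500 bp neither Kdm6a nor Rbfox3 had a peak at an annotated end, and with 2000 bp the Rbfox3 value was 24.3 CPM, at another peak. Peak counts at Kmt2d do not test the genotype, because the labels do not give the allele.

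**Figure D1:**
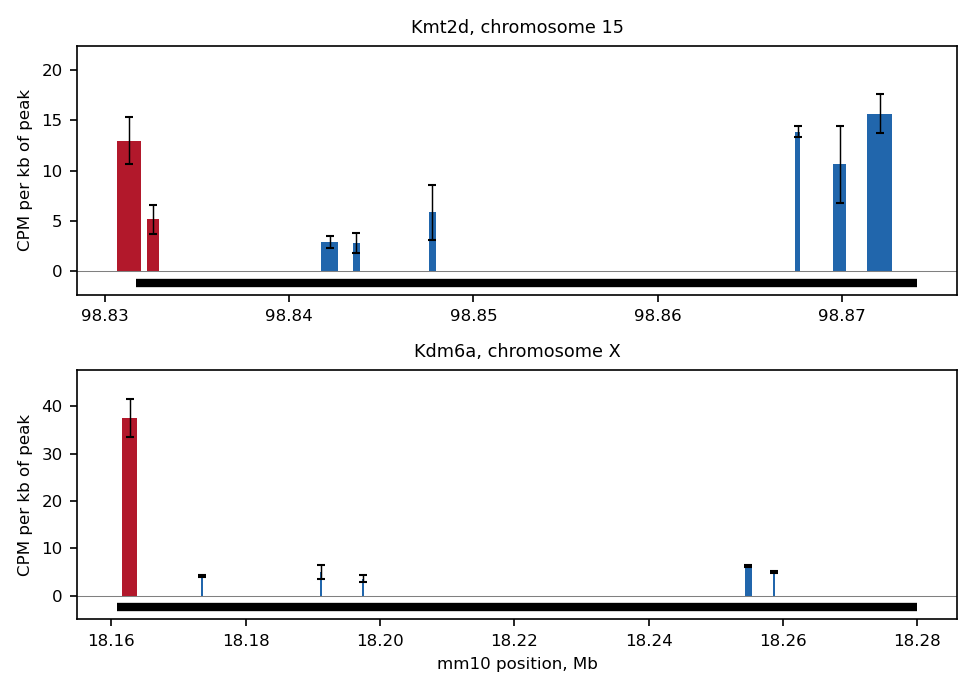
Density of each peak at Kmt2d and Kdm6a in CPM per kb of peak width (mean over 3 libraries, error bars SD) against mm10 position, with peaks within 1000 bp of an annotated gene end in red, other peaks in blue and the annotated gene as a black bar. Kdm6a has 1 strong peak of 84.4 CPM at its left end, and the strongest Kmt2d peak, of 21.7 CPM, lies near its right end.

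Peaks at gene ends were compared with all other peaks, as a measure of how accessibility was divided between gene boundaries and the rest of the genome. Gene-boundary peaks, those overlapping a window of 1000 bp on either side of an annotated end of a protein-coding gene, had a median density of 10.0 ± 0.345 CPM per kb, against 5.08 ± 0.381 at other peaks. The ratio was 1.98-fold, or 0.98 ± 0.14 on the log2 scale, and it was above 0 in 3 of 3 libraries (0.99, 0.84 and 1.12). When not divided by peak width, the log2 ratio was 2.14, with median levels of 12.3 ± 0.252 and 2.79 ± 0.238 CPM. The 17444 gene-boundary peaks made up 10.1% of peaks and held 29.8 ± 1.81% of counts. This share was 30.8% (95% Wilson interval 30.8 to 30.8) in replicate 1, 27.7% (27.7 to 27.7) in replicate 2 and 30.8% (30.8 to 30.9) in replicate 3. Gene-boundary peaks were also wider, with a median of 1130 bp against 575 bp. Of 21887 protein-coding genes, 14956 (68.3%) had a gene-boundary peak. A two-sided exact sign-flip permutation test on 3 libraries gave p = 0.25, the smallest that this test can give with 3 libraries, so it cannot reach 0.05. Gene strand was not used here, so the class joins starts and ends of genes.

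Genes of the neuron types that make up the tissue were compared with random gene lists to describe which cell types the open chromatin belonged to. All 14 markers of dentate granule cells had a gene-boundary peak, with a median level of 37.6 ± 4.40 CPM against 18.3 CPM over all genes with such a peak, at percentile 99.5 of 10000 random lists (adjusted p = 0.0235). Among them were Pdzd2 with 48.5 ± 5.25 CPM, C1ql2, a secreted synaptic organiser of mossy fibres, with 45.2 ± 3.28 CPM, and Calb1, the calcium buffer calbindin, with 49.1 ± 5.38 CPM. Prox1, the transcription factor that specifies granule cells, had 18.1 ± 3.08 CPM at its boundary peak. All 14 pan-neuronal genes had a peak as well, with a median of 37.7 ± 4.03 CPM (percentile 99.3, adjusted p = 0.0317), among them Syt1, the synaptic calcium sensor, with 67.6 ± 7.31 CPM, and the neurofilament gene Nefl with 53.1 ± 4.54 CPM. The 14 excitatory neuron genes all had a peak and a median of 30.6 ± 3.62 CPM, which did not pass (percentile 96.8, adjusted p = 0.0837). Camk2a, a kinase of excitatory synapses, had 49.5 ± 10.7 CPM and the scaffold gene Homer1 56.9 ± 10.7 CPM. The immediate-early genes, which neurons switch on with activity, had a peak in 17 of 19 cases (adjusted p = 0.105 for the share, and 0.0405 with a window of 2000 bp), with a median of 36.0 ± 4.10 CPM (percentile 99.7, adjusted p = 0.0222). Egr1 had 117 ± 22.6 CPM and Jun 111 ± 15.0 CPM, while Egr2 and Npas4 had no gene-boundary peak. When levels were divided by peak width, the granule cell, pan-neuronal and immediate-early medians no longer passed (adjusted p = 0.208, 0.258 and 0.0651).

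Among markers of other neurons and of cells outside the sort, interneuron, oligodendrocyte and vascular genes had low medians. CA pyramidal neuron genes had a peak in 12 of 14 cases and a median of 13.5 ± 2.18 CPM, which did not differ from random lists (percentile 23.3, adjusted p = 0.499). Nectin3 had 38.5 ± 3.70 CPM and Wfs1 14.5 ± 3.64 CPM, and St18 was among those without a boundary peak. Interneuron genes, with a peak in 12 of 15 cases, had a low median of 5.06 ± 0.881 CPM (percentile 0.36, adjusted p = 0.0222). Gad1, which encodes a GABA-synthesising enzyme, stood above the rest of that list with 57.6 ± 9.99 CPM, followed by Adarb2 with 27.7 ± 1.90 CPM. Divided by peak width, Gad1 and Adarb2 were close, with 16.7 ± 2.89 and 16.1 ± 1.11 CPM per kb. Pvalb and Sst had no boundary peak. Oligodendrocyte genes were lowest, with a peak in 8 of 14 cases and a median of 3.63 ± 0.295 CPM (percentile 0.04, adjusted p = 0.0105), although the myelin gene Mbp had 29.4 ± 3.49 CPM and Myrf 8.78 ± 2.34 CPM. Cspg4 and Mag had none. Vascular genes had a peak in 6 of 12 cases and a median of 3.89 ± 0.167 CPM (percentile 0.23, adjusted p = 0.0222). The highest of them, Vtn with 24.7 ± 2.57 CPM, shares its peak with Sarm1 and had none within 500 bp, Kdr had 9.98 ± 0.589 CPM, and Cldn5 and Esam had none. When levels were divided by peak width, the oligodendrocyte and vascular medians no longer passed (adjusted p = 0.0651 for both).

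Microglial genes had a peak in 5 of 14 cases (percentile 0.82 for the share, adjusted p = 0.0587) with a median of 7.41 ± 0.360 CPM (adjusted p = 0.0837), neither of which passed, although the share passed with a window of 500 bp (adjusted p = 0.0230). C1qa had 7.76 ± 0.364 CPM at a peak shared with C1qc (0.873 CPM at another peak with a window of 500 bp), and Aif1 and C1qb had none. C1qc is also a member of this list, so the shared peak is counted for both genes among the 5. Astrocyte genes had a peak in 11 of 12 cases and a median of 12.4 ± 0.834 CPM (percentile 19.0, adjusted p = 0.438). The glutamate transporter gene Slc1a2 had 35.1 ± 3.12 CPM, Aldoc had 14.8 ± 2.09 CPM at a peak shared with Pigs, and Aldh1l1 had none. Genes of adult neurogenesis had a peak in 14 of 15 cases and a median of 7.42 ± 0.692 CPM (percentile 2.24, adjusted p = 0.0837, and 0.0268 with a window of 500 bp). Sox11 had 64.8 ± 7.20 CPM, Mcm2 11.9 ± 1.07 CPM, and Eomes none. Only 2 of the 16 posterior patterning genes, transcription factors of the trunk, limbs and heart, had a peak (percentile 0, adjusted p = 0.0030). These were Hoxa9 with 6.92 ± 2.07 CPM and Hoxc6 with 1.40 ± 0.185 CPM, so that their median of 4.16 ± 1.12 CPM (percentile 0.06, adjusted p = 0.0105) rests on 2 genes, neither with a peak within 500 bp, and Evx1 and Hoxa13 were among the rest. Several members are neighbours, such as Hoxa2, Hoxa5, Hoxa9 and Hoxa13 between 52162417 and 52260880 on chromosome 6. Random lists draw genes singly and so treat neighbours as independent, which may make the p-values of this list too small. Genes of other organs had a peak in 7 of 16 cases and a median of 8.68 ± 0.952 CPM (adjusted p = 0.0837). Sftpc had 28.7 ± 2.19 CPM at a peak shared with Bmp1. Acta1 had 22.5 ± 1.42 CPM at a peak shared with no other protein-coding gene, and Actn3 17.8 ± 0.911 CPM at a peak shared with Zdhhc24. Alb was among those without a peak. Genes of histone-modifying machinery had a peak in 21 of 23 cases (adjusted p = 0.0495 for the share) and a median of 28.4 ± 1.14 CPM (percentile 96.8, adjusted p = 0.0837). Kmt2b had 44.9 ± 7.79 CPM at a peak shared with Zbtb32, and Ash2l and Dpy30 had none. All 14 housekeeping genes had a peak, with a median of 21.0 ± 1.07 CPM (percentile 60.9, adjusted p = 0.783), among them Polr2a with 70.0 ± 9.35 CPM, shared with Slc35g3, and Eef1a1 with 55.0 ± 5.94 CPM. The 4 lists in which all members had a peak (granule cell, excitatory, pan-neuronal and housekeeping) passed for that share (adjusted p = 0.0312 for each). None of these 4 shares, nor that of the histone genes, passed against random lists matched on gene length (adjusted p = 0.0585 to 0.321) or with a window of 2000 bp (0.0613 to 0.110), and with 500 bp the granule cell share alone of the 5 passed.

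**Figure D2:**
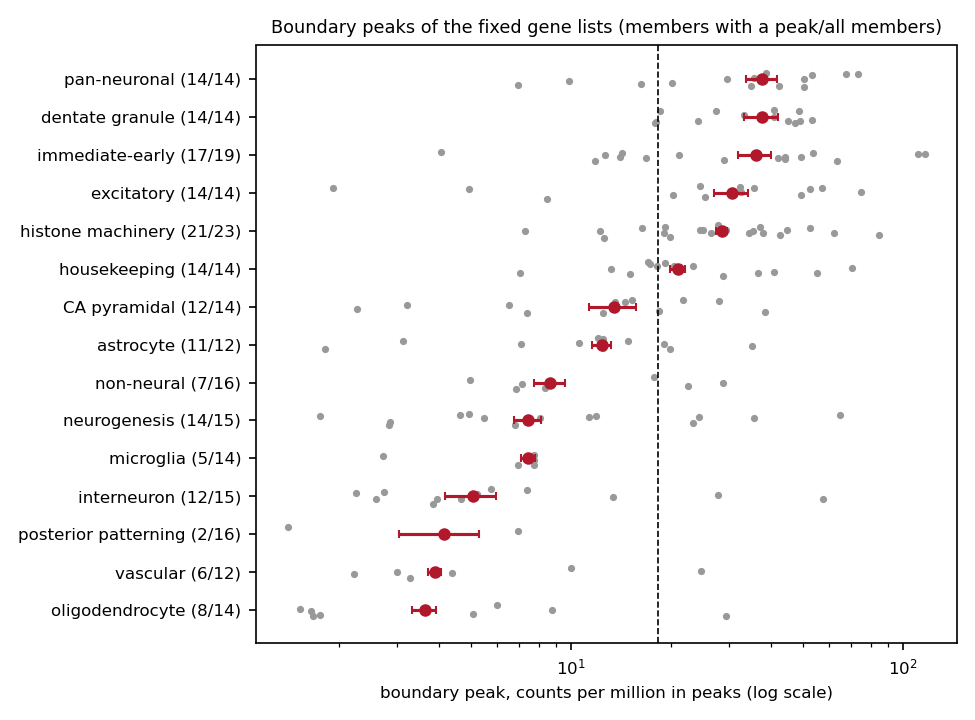
Level of the strongest gene-boundary peak of each member of the 15 gene lists (grey points, mean over 3 libraries), and the median per list as mean ± SD over 3 libraries (red), in CPM on a log scale. The dashed line marks the median over all protein-coding genes with such a peak, 18.3 CPM. The granule cell and pan-neuronal medians of 37.6 and 37.7 CPM lie to its right and the oligodendrocyte median of 3.63 CPM is the lowest.

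Pairs of these lists were then compared directly, to set neuron types against each other and against glia. Gene-boundary peaks of granule cell markers were 2.70-fold above those of CA pyramidal markers (log2 1.43 ± 0.19, permutation test, adjusted p = 0.000693) and 4.47-fold above those of interneuron markers (log2 2.16 ± 0.29, permutation test, adjusted p = 0.000600). Excitatory genes were 3.20-fold above interneuron genes (permutation test, adjusted p = 0.00496). Pan-neuronal genes were 2.77-fold above astrocyte genes (permutation test, adjusted p = 0.00237), 6.21-fold above oligodendrocyte genes (exact permutation test, adjusted p = 0.000600), 4.54-fold above microglial genes and 4.96-fold above vascular genes (exact permutation tests, adjusted p = 0.00149 for both). Immediate-early and housekeeping genes did not differ at their boundary peaks (1.27-fold, permutation test, adjusted p = 0.370). These ratios use CPM not divided by peak width, and ratios of levels divided by width were not computed. They cover only members with a peak, which were 8 of 14 oligodendrocyte, 5 of 14 microglial and 6 of 12 vascular genes. The peak shared by the microglial genes C1qa and C1qc is counted for each of them. The tests were two-sided, across genes, which are not independent replicates, and were adjusted over 8 pairs. Because these 8 pairs were chosen after values of single genes had been seen, their p-values are not those of comparisons fixed in advance.

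Peaks away from gene ends, which are often more specific to a cell type, were summed over each gene with 10000 bp on both sides and divided by the length of that span. A promoter inside a span and outside the windows at gene ends would be counted here, so these values may include promoters. Excitatory neuron genes had a median of 1.23 ± 0.114 CPM per kb, immediate-early genes 1.23 ± 0.0841 and granule cell genes 0.800 ± 0.0615, against 0.15 over all protein-coding genes. These 3 lists lay at percentile 100 of random lists of matched length (adjusted p = 0.0010 for each, the smallest that 10000 lists can give here). Camk2a had 3.82 ± 0.0605 CPM per kb, Prox1 2.65 ± 0.495 and Bdnf, an activity-regulated growth factor, 2.52 ± 0.275. Npas4 and Egr2, without a boundary peak, had 1.69 ± 0.125 and 1.62 ± 0.239, and whether their promoters are part of this was not tested. Pan-neuronal genes also lay high, with 0.623 ± 0.00649 CPM per kb (percentile 99.7, adjusted p = 0.0270), among them Celf4 with 2.47 ± 0.207. The other 11 lists did not pass, although posterior patterning genes passed as low with 50000 bp on each side (adjusted p = 0.00540). Their percentiles were 88.2 for vascular, 87.6 for neurogenesis, 86.6 for oligodendrocyte, 78.3 for astrocyte, 73.1 for CA pyramidal, 69.9 for interneuron, 63.5 for microglial, 44.2 for other organs, 40.5 for housekeeping, 20.9 for histone and 5.86 for posterior patterning genes.

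Between pairs of lists, immediate-early genes had 3.53-fold the span density of housekeeping genes, excitatory genes 3.23-fold and granule cell genes 2.65-fold that of interneuron genes (permutation tests, adjusted p = 0.00117 for each). Granule cell genes lay 2.31-fold above CA pyramidal genes (permutation test, adjusted p = 0.00624). Pan-neuronal genes lay 2.42-fold above microglial genes and 2.19-fold above vascular genes (permutation tests, adjusted p = 0.0151 and 0.0367). Their ratios to astrocyte and oligodendrocyte genes, 1.90-fold and 1.91-fold, did not pass (permutation tests, adjusted p = 0.0534 for both). Unlike the percentiles above, these pair tests were not matched on gene length. Span density differed with length, with a median of 0.297 CPM per kb over genes of at least 50000 bp against 0.15 over all. Differences in length between lists may therefore enter these ratios.

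**Figure D3:**
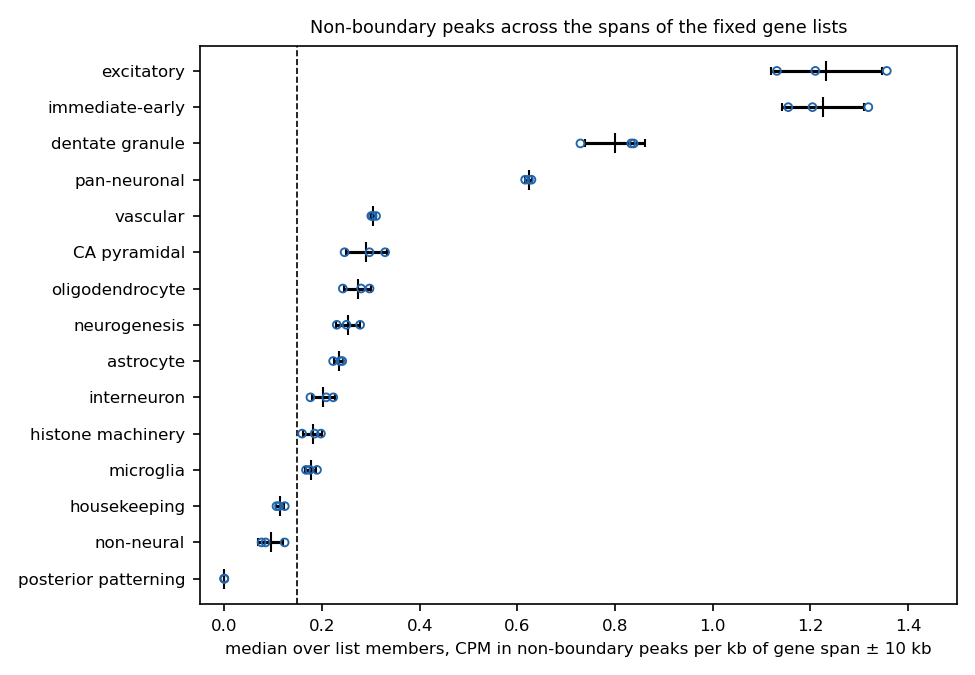
Median over list members of the summed level of peaks away from gene ends, in CPM per kb of the gene with 10000 bp on both sides, per library (blue circles) and as mean ± SD over 3 libraries (black). The dashed line marks the median of 0.15 over all protein-coding genes, and the excitatory and immediate-early lists, both at 1.23, lie farthest to its right.

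The 4 strongest peaks by density lay away from gene ends. The 5 strongest peaks away from gene ends were the last listed peaks of chromosomes 14, 12, 7, 18 and 16, from 124801553, 120028663, 145340926, 90602183 and 98107511. Their nearest genes of any kind were Fgf14 at 123867 bp, Tmem196 at 7421 bp, Mrgprd at 16867 bp, Gm45871 at 8459 bp and A630089N07Rik at 25072 bp. The peak on chromosome 14 had 704 ± 233 CPM over 685 bp. At gene boundaries the highest density was at the last listed peak of chromosome 3 (159939405 to 159939678), 739 bp from Wls, with 201 ± 63.4 CPM. With a window of 500 bp the Wls value was 19.4 CPM, at another peak. It was followed by peaks of Gm40364 and Gm40363 (1 shared peak of 174 ± 15.0 CPM), Gm40365, Gm40369, Gm40367 and Gm36327, which stand side by side on chromosome 6. Whether these predicted genes are near-identical copies that share reads was not tested, and their values are uncertain. Next came Tsga10 with 96.8 ± 8.82 CPM and a peak shared by Usp5 and Cdca3 with 107 ± 17.2 CPM.

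The 3 libraries were then compared with each other to set the error behind every value. Across peaks, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.943 for replicates 1 and 2, 0.947 for 1 and 3 and 0.943 for 2 and 3, with Spearman's rho of 0.905, 0.903 and 0.907. Beyond counting error, peaks varied by a coefficient of 13.7% over 171764 peaks, 13.9% at gene boundaries and 13.6% elsewhere. This order turned without replicate 2 (9.75% at gene boundaries and 13.8% elsewhere) and when each library's trend with peak density was removed, a setting chosen after the data were seen (7.95% and 12.3%). The coefficient fell with counts, from 19.0% in the lowest quartile of peaks by total count to 12.8% in the highest. Gene-boundary and other peaks, with median total counts of 321 and 72, were not matched on counts for it. A chi-square test of each peak's 3 counts, with Benjamini-Hochberg adjustment, found 9134 peaks (5.32%) that differed between libraries by more than counting error. They made up 20.4% of gene-boundary peaks and 3.61% of other peaks, and 17.6% of other peaks when these were reweighted to the counts of gene-boundary peaks. With the density trend removed, 2284 peaks differed, 2.71% of gene-boundary and 1.17% of other peaks. In 3755 of the 9134, replicate 2 was the farthest library and low. Leaving out replicate 2 left 2112 such peaks, against 4728 without replicate 1 and 5224 without replicate 3. In replicate 2, peaks in the highest of 20 density bins had a median log2 ratio of -0.22 to the mean of the others, and those in the lowest bin had 0.14.

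**Figure D4:**
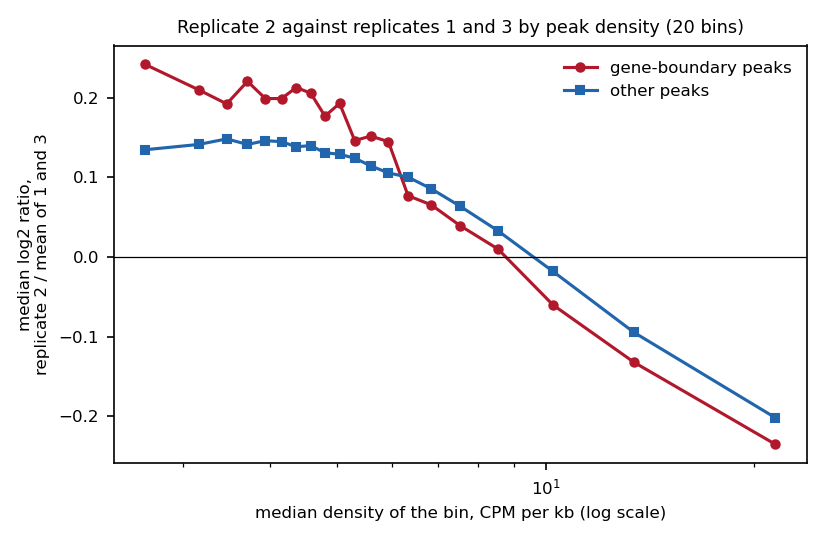
Median log2 ratio of replicate 2 to the mean of replicates 1 and 3 in 20 equal bins of peak density (CPM per kb, log scale), for gene-boundary peaks (red) and other peaks (blue). Over all peaks the ratio is 0.14 in the lowest bin and -0.22 in the highest.

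The gene-boundary peaks with the most uneven counts for their level included those of Rnft2, Eps8l1, Cryab with 2310030G06Rik, Edc3 with Clk3 (2 peaks), Bag6 with Prrc2a, Cstf3, Asmt and St8sia5. The Asmt peak (chromosome X, 170672807 to 170673876) had 7.0 CPM in replicate 1, 19.2 in replicate 2 and 8.14 in replicate 3 (adjusted p = 1.25e-09, chi-square of counts in these 3 libraries). The Rnft2 peak (chromosome 5, 118191449 to 118192403) had 1.75, 5.69 and 1.91 CPM in the same order, and the St8sia5 peak (chromosome 18, 77185340 to 77186270) had 6.54, 5.69 and 1.68 CPM. This test compares these libraries and not conditions. The Asmt peak lies towards the end of chromosome X, whose last listed peak starts at 170880924 and was also highest in replicate 2. Whether reads of repeated sequence enter the Asmt peak was not tested.

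On the sex chromosomes, X peaks held 2.38%, 2.21% and 2.15% of counts in replicates 1, 2 and 3, and Y peaks 0.0424%, 0.0347% and 0.0364%. The 95% Wilson intervals for Y were 0.0412 to 0.0436, 0.0334 to 0.0362 and 0.0351 to 0.0377, which cover counting error only. X peaks numbered 4467 and Y peaks 32.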

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

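The density-trend offsets, the leaving out of the 100 strongest peaks and the random lists matched on gene length were chosen after the data were seen. No result that passed its test and was run under other settings changed direction. The comparisons between pairs of lists were not run under other settings. Of 224 percentiles of lists under other settings, 6 crossed the middle of the random lists, all for lists that passed under neither setting, such as the histone span (20.9 to 83.9) and housekeeping span (40.5 to 85.8) with 50000 bp on each side. The order of the variation coefficients at gene-boundary and other peaks turned, as given below. The log2 ratio of gene-boundary to other peaks was 2.14 when not divided by peak width, 1.14 with a window of 500 bp and 0.77 with 2000 bp, and the boundary share of counts was 32.8% with 2000 bp. Mean Pearson r between replicates was 0.928 with a pseudocount of 0.25 and 0.964 with 5. For levels divided by peak width, the percentiles of list medians that no longer passed were 91.7 for granule cell, 88.8 for pan-neuronal, 98.5 for immediate-early, 0.75 for oligodendrocyte and 1.48 for vascular genes. For shares of members with a peak, a window of 500 bp ended the calls of excitatory (percentile 99.0), pan-neuronal (99.1), histone (99.0) and housekeeping genes (99.2). A window of 2000 bp ended those of granule cell (99.3), excitatory (99.4), pan-neuronal (99.4), histone (98.1) and housekeeping genes (99.3). Length-matched lists ended those of granule cell (98.2), excitatory (98.6), pan-neuronal (98.4), histone (92.2) and housekeeping genes (99.8). Calls were gained for the microglial share (0.10) and the neurogenesis median (0.60) at 500 bp, the immediate-early share (99.9) at 2000 bp and the posterior patterning span (0.08) with 50000 bp on each side. At 500 bp the posterior patterning list had no boundary peak and hence no median. The cause of these moves was not tested.

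The coefficient of variation was 12.6% over all peaks and 12.7% at other peaks for mean counts of at least 20. With density-trend offsets it was 11.3% over all peaks, 7.95% at gene-boundary and 12.3% at other peaks. Leaving out each replicate in turn gave 12.9 to 14% over all peaks, 9.75 to 15.8% at gene-boundary peaks and 13.3 to 13.8% at other peaks, each lowest value but the last without replicate 2. Peaks that varied numbered 4047 at an adjusted p of 0.01, 2284 with the offsets (2175 of them among the 9134) and 2112 to 5224 with a replicate left out, the lowest without replicate 2. Fewer counts enter a test with a replicate left out. Of the other values for comparisons, 249 kept their call or stayed within the spread between libraries. For single named peaks 195 values stayed within the spread and 6 moved, among them Kmt2d (21.7 CPM with 2000 bp). With a window of 500 bp, 9 of 42 named genes had no boundary peak and so no value: Kdm6a, Rbfox3, Vtn, Hoxa9, Hoxc6, Tsga10, Gm36327, Gm40367 and Gm40369. Depth limits weak peaks most. No paired analysis was possible because only 1 group was analysed. Alternatives that need sequence, on CpG islands and GC content, were not run.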

Other observations

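Among 4945 protein-coding genes of at least 50000 bp, a list drawn up after the data were seen, several of those with the densest peaks away from gene ends have known roles in neurons. The median over these genes was 0.297 CPM per kb (n = 3 libraries throughout). Synpo, which encodes an actin-binding protein of dendritic spines, had 4.09 ± 0.238 CPM per kb with 17 peaks in its span, and Camk2a, also on chromosome 18, had 3.82 ± 0.0605 with 27. The transcription factor genes Nfix, Prox1, Bcl11a, Tcf4 and Bcl11b had 3.32 ± 0.264, 2.65 ± 0.495, 2.63 ± 0.0977, 2.27 ± 0.167 and 2.25 ± 0.241. Cplx2, a regulator of synaptic vesicle release, had 2.30 ± 0.189, and Nrp2, a guidance receptor, had 2.18 ± 0.0389. Gm40363 and Tmem196, with 12.6 ± 1.42 and 3.81 ± 1.14, have spans that take in peaks of the chromosome 6 cluster and the last listed peak of chromosome 12. No test was run on this ranking.

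The genes with the most peaks in their span were long ones. Tenm2 held 171 peaks over 1230 kb, Dab1 169 over 1125 kb, Celf2 159 over 857 kb, and Magi2 and Rbfox1 158 each. Kalrn, an exchange factor of dendritic spines, held 149 peaks over 604 kb, and Tcf4 130 over 345 kb.

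For the patterns weighed below, both tests on the last listed peaks of chromosomes, and the form of the background test, were chosen after the result was seen. Replicate 2 had a flatter profile than the other libraries, with a median log2 ratio to them of 0.14 in the weakest of 20 density bins and -0.22 in the strongest. A different share of glia or vascular cells would set apart from neuronal peaks those marker peaks that are open in such cells. At matched density the medians differed by -0.00273 on the log2 scale (95% bootstrap interval -0.054 to 0.041, permutation p = 0.934, 278 and 1376 peaks). No such shift was seen. Whether peaks at glial and vascular marker genes are open in those cells rather than in neurons was not tested. The test therefore cannot exclude a different share, and another mix of neuron types was not tested. More background in replicate 2 would move gene-boundary and other peaks of matched density alike, within 0.1. The test was run in 3 forms: pooled medians differed by -0.000134, a mean over 50 bins gave 0.000965, and because the 20 bins went both ways (-0.0421 to 0.107) these near-zero values decide nothing, so the bin of largest difference is used, 0.107 (interval 0.0780 to 0.134). Picked as the largest of 20, this value may overstate the difference, and the next largest was 0.0792, within the limit of 0.1. As the interval of 0.0780 to 0.134 spans 0.1, background may or may not account for the pattern. The lower depth of replicate 2 and differences between animals stay open as well.

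The last listed peaks of several chromosomes were among the strongest peaks: of 21 such peaks, 12 were in the strongest 100. Reads of repeated sequence that is placed on few copies in the reference are a candidate source: the 21 peaks had a median log2 ratio of 0.60 in replicate 2 over the others, higher in 16 of 21, where the 1000 strongest other peaks had -0.28. Elements regulating nearby genes stay open. Of the 12, 5 lay within 10000 bp of an annotated gene of any kind, against 97% of the other 1000 (Fisher's exact test, p = 3.38e-08). This contrast cannot decide, because the 12 were picked by their position at a chromosome end, which bears on their distance from genes. Strong peaks also often lie at gene ends: the highest of 20 density bins held 4998 gene-boundary and 3630 other peaks. Elements acting from beyond 10000 bp were not covered. The rise in replicate 2 is not limited to the last listed peaks. On chromosome 9, from 3003334 to 3030905, lay 8 of the 25 strongest peaks. They are far from its last listed peak, which starts at 124422847, but near the start of the chromosome, so they too lie towards an end. All 8 were highest in replicate 2, as were 21 of the 25. Sequence was not used here, so repeat content was not looked at directly, and no biological explanation other than nearby genes was tested.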
